A study of Papio anubis with 40 samples.

How the data were processed

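Small RNA was sequenced from 40 plasma samples of 8 olive baboons (Papio anubis), each bled at 5 time points: before inoculation (month 0) and 3, 6, 9 and 15 months after endometriosis was induced by placing menstrual tissue in the peritoneal cavity. Each sample was 0.5 mL of plasma per the labels, while the description of the series speaks of serum. No animal without inoculation is among the samples analysed here, so time since inoculation, age of the animal and storage of the sample move together. The library numbers in the labels run baboon by baboon and, within each baboon, in order of month. Whether libraries were processed in that order is not stated. If they were, position in the order cannot be told apart from baboon or month.

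The deposited table holds whole-number counts per mature microRNA name, not normalized. Per the labels, adapters were ligated to the microRNA ends, molecular identifiers were assigned at cDNA synthesis and the libraries were run on an Illumina NovaSeq X. Whether the counts are of molecular identifiers or of reads is not stated, and the aligner and the microRNA database are not given in the sources used here. The labels name R 4.5.0, edgeR and limma. The series description also speaks of tRNA fragments; the table analysed holds microRNAs. Rows carry human names, and no baboon coordinates came with them, so none are given. Some rows join several names with a slash, and such a row cannot be divided between its members.

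The table has 2731 rows, of which 689 had a count in any library. Rows were kept with filterByExpr of edgeR grouped by month (minimum count 10, minimum total count 15), which left 318 rows holding 99.98% of the counts; 21 of them are joined names. Total counts per library ran from 696873 to 5824111 with a median of 1629264.5. A count of 0 in a library allows up to 3 counts, which is 0.374 to 3.97 CPM (counts scaled to a common library total) depending on the library. Shares of counts are given with exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only and treat the counts as independent. The counts cannot be taken as independent molecules, so the intervals may be too narrow and the floors too low.

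Counts were scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) in a single fit of all 40 samples, with month and baboon as terms, so each comparison was paired by animal. Months 3, 6, 9 and 15 were each compared with month 0. The 4 months were also tested together (any month), as their mean against month 0, and as the mean of months 9 and 15 against the mean of months 3 and 6 (late against early). P-values were adjusted by the Benjamini-Hochberg method over the rows tested, with a threshold of 0.05, and all tests were two-sided. Log2 fold changes are printed with their standard error (SE), and CPM values are TMM-scaled means with the SD over the 8 baboons. The fit was tested on simulated data drawn from a model of these counts. At month 15 it recovered, of changed rows kept by the filter, 4.62% of those changed 1.5-fold, 25.2% at 2-fold and 75.5% at 4-fold. Changed rows that the filter removed are not in these shares. In each of the 10 simulated sets 200 rows were changed before filtering, far more than were called in the real data. With fewer changed rows the adjustment is stricter, and the fit would be expected to recover smaller shares. Of its calls 5.71% were false, and 2 of 10 simulated sets without any change gave a call.

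Comparisons, lists, the naming rule and most alternatives were fixed before the data were examined. For each month, and for late against early, the microRNAs named are the 10 with the largest rise and the 10 with the largest fall past the threshold whose own change had that sign in at least 7 of 8 baboons. Where fewer than 10 passed, the 10 with the smallest p are named, as values. For the any-month test the 10 with the smallest p count, with no sign rule. Also named are miR-451a and miR-23a-3p (present only as the joined row miR-23a-3p/23b-3p), the 10 microRNAs with the highest mean CPM, and up to 4 tested members of each list with the smallest p in the any-month test.

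The lists were erythrocyte, platelet, myeloid, lymphocyte, liver, muscle, neural, epithelial, endothelial and stromal, endometriosis, let-7, miR-17 clusters, DLK1-DIO3, C19MC, inflammation, and fibrosis and hypoxia. They held 280 entries, 231 of them distinct, and 4 had no matching name in the table. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the lists within a comparison. Members were also adjusted over their own list alone, with no correction over the lists or the comparisons.

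A haemolysis index was taken per library as log2 CPM of miR-451a minus log2 CPM of miR-23a-3p/23b-3p (prior count 2). The index, the log2 total count and the number of rows with a count were compared with month 0 by exact paired sign-flip permutation tests over the 8 baboons, for which the smallest possible p is 0.00781, adjusted over the 4 months. Shares of variance came from two-way sums of squares on log2 CPM per microRNA, with 100 permutations of the labels.

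Alternatives covered the scaling (DESeq2 size factors, upper-quartile factors, library totals alone), the filter (none except 1 count, or a mean count of 50 or more), the test (DESeq2 1.42.0, limma-voom with the baboon as a fixed or a random effect, robust dispersion), the fit without the baboon block, fits of the compared months alone, the haemolysis index or the log2 total count as a covariate, and leaving out each baboon in turn. Alternatives added after seeing the data were taking miR-122-5p out before scaling, its log2 level as a covariate, and leaving out the month 9 library of PA8001 or the month 15 library of PA8872. No library was left out of the reported values.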

Results

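Mature microRNAs were counted in 40 plasma libraries from 8 baboons, 8 libraries at each of months 0, 3, 6, 9 and 15. Total counts ran from 696873 to 5824111 per library (median 1629264.5), and 266 to 492 microRNA rows had a count (median 352.5). None of the 780 pairs of libraries was identical. Libraries of a baboon resembled each other: the deviations of microRNAs from the mean of their month had a mean correlation across microRNAs of 0.208 between libraries of the same baboon and of -0.029 between libraries of different baboons. The correlation is across microRNAs, which are not independent replicates.

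The most abundant microRNA was miR-16-5p, a microRNA of red blood cells, with a mean of 211560 CPM over the 40 libraries. It was followed by miR-122-5p, the main microRNA of hepatocytes, at 176760 CPM, and by the red cell microRNA miR-486-5p at 99519 CPM. The mean of miR-122-5p rests largely on PA8001, whose month 9 library had 2196000 CPM after TMM scaling. miR-126-3p, which is abundant in endothelium and platelets, had 60525 CPM and miR-126-5p had 29495 CPM. The let-7 family was represented by let-7b-5p at 55878 CPM, let-7a-5p/7c-5p at 50390 CPM, let-7g-5p at 46987 CPM and let-7f-5p at 27592 CPM, and miR-93-5p had 27907 CPM. miR-16-5p had the highest count in 31 libraries, miR-122-5p in 8 and miR-126-3p in 1.

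The share of miR-122-5p varied widely between libraries. Its lowest share was 0.307% of counts in the month 6 library of PA8912 (95% CI 0.302 to 0.311%), and its highest was 78.6% in the month 9 library of PA8001 (95% CI 78.59 to 78.68%), with a median of 4.90% over the 40 libraries. In PA8001 the share was 52.9% before inoculation, 40.2% at month 3, 51.0% at month 6 and 10.6% at month 15. Its log2 CPM did not differ from month 0 at any month by the exact sign-flip test (smallest adjusted p = 0.234), and it was higher in 5 of 8 baboons at month 9, with a mean difference of 1.12 ± 1.74 (SD, n = 8).

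**Figure D1:**
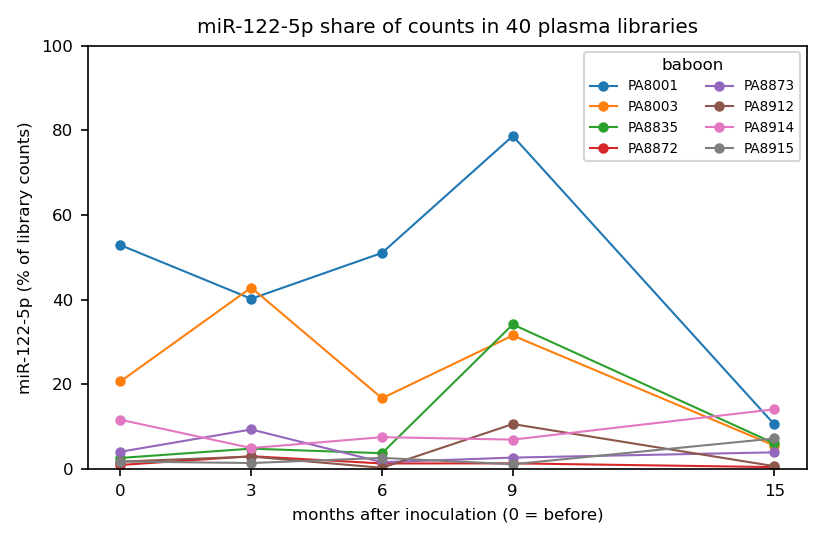
Share of library counts in miR-122-5p (vertical axis, percent) against months after inoculation (horizontal axis), with 1 line per baboon and 1 point per library. PA8001 reached 78.6% at month 9, while the median over the 40 libraries was 4.90%.

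Month 15 was compared with month 0 to find microRNAs that differed in plasma at the last time point. miR-210-3p, a microRNA induced by hypoxia, rose 2.53-fold, from 151 ± 38.5 to 366 ± 90.1 CPM (SD, n = 8), in 8 of 8 baboons (log2 1.34, SE 0.239, adjusted p = 0.000959 by edgeR). miR-30e-5p rose 1.97-fold in 8 of 8 baboons, from 9054 ± 3245 to 17054 ± 4168 CPM (log2 0.98, SE 0.209, adjusted p = 0.00715). miR-126-3p rose from 48663 ± 18107 to 79585 ± 19895 CPM, also in 8 of 8 baboons (log2 0.72, SE 0.213, adjusted p = 0.0448). In the other direction miR-34c-5p, a p53 target that is abundant in ciliated epithelia, fell from 33.5 ± 47.8 to 1.82 ± 1.96 CPM. It was lower in 7 of 8 baboons, and PA8001 had no count at either time (log2 -3.93, SE 0.896, adjusted p = 0.0118). Its month 15 libraries held 0 to 9 counts, 3 of them 0, so the size of this fold is poorly set; without PA8912, which held 298 of the 480 counts at month 0, it no longer passed (log2 -3.08, adjusted p = 0.0995), nor did it with log2 total count as a covariate (log2 -3.25, adjusted p = 0.0672). miR-100-5p fell from 165 ± 115 to 68.5 ± 40.3 CPM in 7 of 8 baboons (log2 -1.16, SE 0.302, adjusted p = 0.0344). Within baboons miR-100-5p followed miR-122-5p (r = 0.71), and its log2 change was -1.17 with the level of miR-122-5p as a covariate (adjusted p = 0.00489).

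In all, 13 of 318 microRNAs passed the threshold at month 15, 8 higher and 5 lower. Of the 318, 40 had an unadjusted p under 0.05, where 15.9 would be expected by chance, here and in each other comparison. Further rises were miR-4676-5p (log2 1.17, 7 of 8 baboons), the neutrophil and monocyte microRNA miR-223-5p (log2 0.83, 7 of 8), miR-191-3p (log2 0.73, 8 of 8) and miR-1307-3p (log2 0.66, 8 of 8). Further falls were miR-342-3p (log2 -0.81, 7 of 8 baboons) and miR-181a-5p (log2 -0.65, 8 of 8), both abundant in lymphocytes. miR-187-3p (log2 1.05) and miR-671-5p (log2 -0.81) moved in their direction in 6 of 8 baboons, fall outside the naming rule and are named after their values were seen. Adjusted p-values of these 8 ran from 0.0192 to 0.0448. The median log2 change over all 318 rows was 0.11, against 0.00090 with DESeq2 size factors and -0.0079 with upper-quartile factors, and the changes above are to be read relative to that shift. The division into rises and falls moved with it: 4 rose and 6 fell with DESeq2 size factors, 2 rose and 7 fell with upper-quartile factors, and 2 rose and 2 fell with library totals alone. The count also depended on single animals, being 7 without PA8001, 4 without PA8003, 4 without PA8835, 3 without PA8872, 5 without PA8873, 2 without PA8912, 6 without PA8914 and 20 without PA8915. It was 4 without the month 15 library of PA8872, 3 with the haemolysis index as a covariate, 2 with log2 total count as a covariate, 8 with miR-122-5p taken out, 8 with its level as a covariate, 2 with no replicate block for the baboon, and 0 in a fit of months 0 and 15 alone. miR-210-3p passed in 24 of 25 alternatives, miR-30e-5p in 23 of 25, miR-100-5p in 13 of 25 and miR-126-3p in 6 of 25. Among the other rises miR-1307-3p passed in 9 of 25, miR-187-3p in 8, miR-223-5p in 7, and miR-191-3p and miR-4676-5p in 5 each. Among the other falls miR-34c-5p passed in 21 of 23, miR-181a-5p and miR-342-3p in 14 of 25 each and miR-671-5p in 12 of 25.

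**Figure D2:**
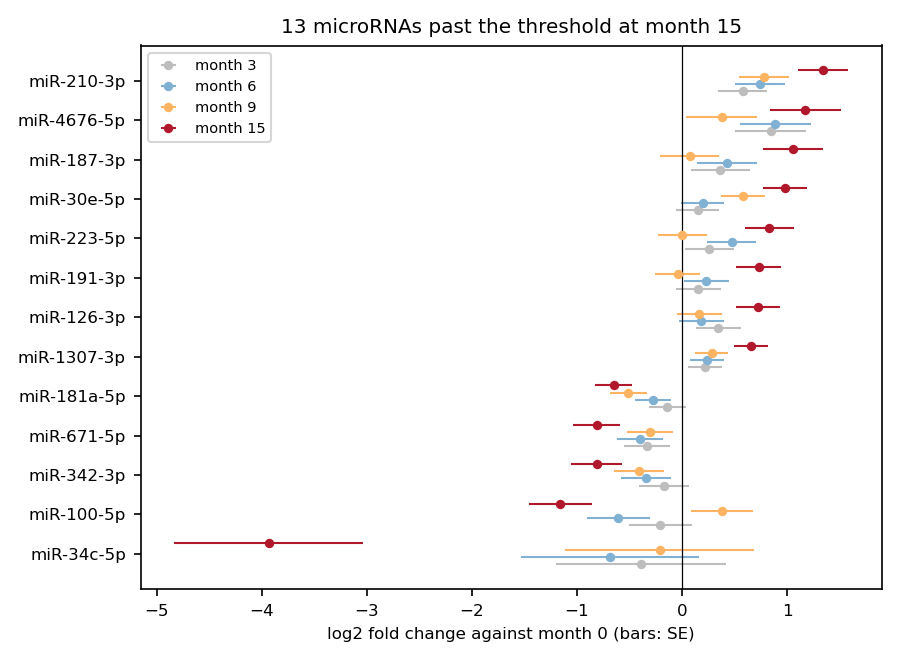
Log2 fold change against month 0 (horizontal axis; bars are SE) for the 13 microRNAs past the threshold at month 15 (vertical axis), at months 3, 6, 9 and 15. miR-210-3p lies at 1.34 at month 15 and at 0.57, 0.74 and 0.78 at months 3, 6 and 9, and miR-34c-5p lies at -3.93 at month 15.

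**Figure D3:**
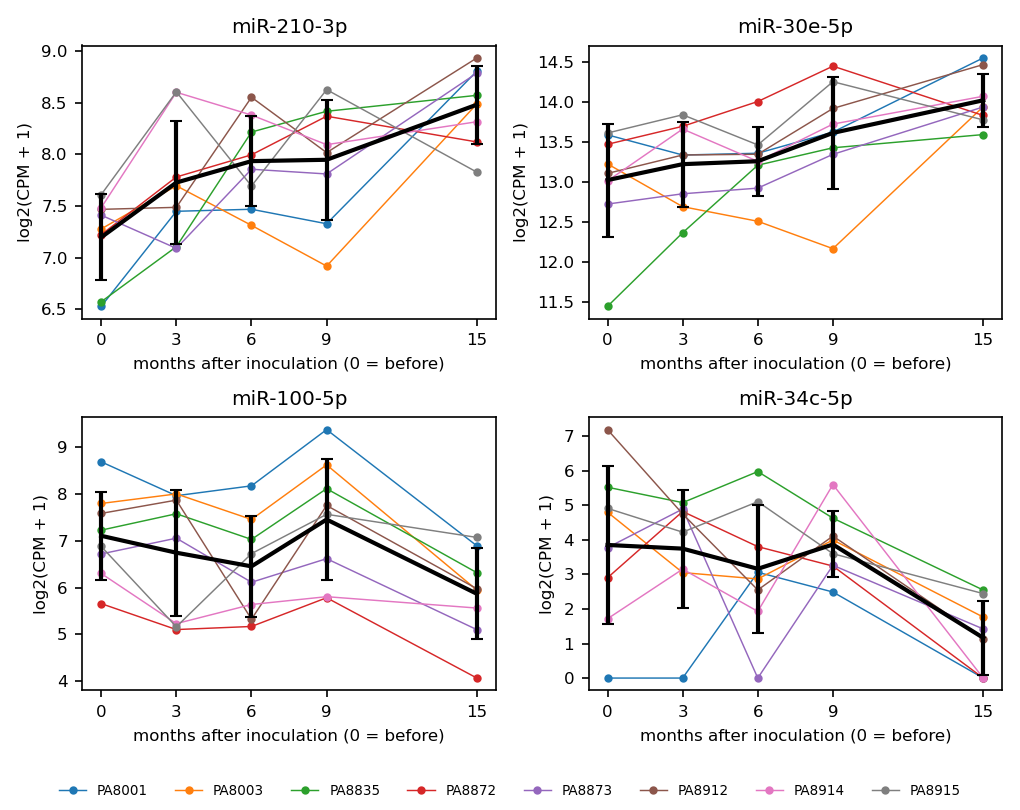
Log2 of CPM plus 1 (vertical axes) against months after inoculation (horizontal axes) for miR-210-3p, miR-30e-5p, miR-100-5p and miR-34c-5p, with 1 coloured line per baboon and the mean with its SD in black (n = 8). miR-210-3p and miR-30e-5p were higher at month 15 than at month 0 in 8 of 8 baboons; miR-100-5p was lower in 7 of 8.

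The lists of cell and tissue markers showed a limited picture at month 15. The epithelial list (miR-200 family and others) was lower as a set, with 7 of 9 tested members below 0 and a median log2 change of -0.66 (camera adjusted p = 0.0340). This call was lost with an estimated correlation (adjusted p = 0.627), with fry (adjusted p = 0.317), without the month 9 library of PA8001 (adjusted p = 0.0555) and without the month 15 library of PA8872 (adjusted p = 0.193). None of its members passed over all microRNAs tested; adjusted over the list alone 1 did, miR-200a-3p (log2 -1.87, SE 0.616, lower in 7 of 8 baboons). Of 11 lymphocyte microRNAs, miR-30e-5p rose and miR-181a-5p and miR-342-3p fell, both over all microRNAs tested and adjusted over the list alone (median -0.29, adjusted p = 0.0583). Of 12 endothelial and stromal microRNAs, 9 lay below 0 with a median of -0.32 (adjusted p = 0.0583). miR-100-5p fell over all microRNAs tested, and adjusted over the list alone miR-99a-5p was lower (log2 -0.85, SE 0.265) and miR-221-3p higher (log2 0.86, SE 0.276). The platelet list lay above 0 in 10 of 12 members with a median of 0.41 (adjusted p = 0.0749), and miR-126-3p rose both over all microRNAs and adjusted over the list alone. In the myeloid list 6 of 10 members lay above 0 with a median of 0.26 (adjusted p = 0.308), and miR-223-5p rose by both counts. Beside these lists, the mean haemolysis index was 0.83 lower and the mean log2 total count 0.69 higher at month 15 than at month 0, and neither difference passed its exact test.

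Lists tied to the disease or to signalling did not pass at month 15. Of 25 endometriosis microRNAs, 14 lay above 0 and 11 below (median 0.03, and -0.07, -0.09 and -0.04 with DESeq2 size factors, upper-quartile factors and library totals alone; adjusted p = 0.374), the mean of -0.14 and the direction of the test having the opposite sign to the median. miR-34c-5p and miR-342-3p fell over all microRNAs tested, and adjusted over the list alone miR-200a-3p was added, which makes 3. In the fibrosis and hypoxia list 9 of 13 lay below 0 (median -0.17, adjusted p = 0.402), and miR-210-3p rose by both counts. In the inflammation list 7 of 12 lay above 0 (median 0.19, adjusted p = 0.374), and miR-187-3p rose by both counts.

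No member passed by either count in the remaining lists at month 15. DLK1-DIO3, an imprinted cluster, lay above 0 in 26 of 28 members with a median of 0.46 (adjusted p = 0.0749). The let-7 family had 7 of 8 members above 0 (median 0.24, adjusted p = 0.374) and the miR-17 clusters 7 of 11 (median 0.22, adjusted p = 0.374). Medians were -0.14 for the erythrocyte list (adjusted p = 0.374), -0.19 for liver (adjusted p = 0.310), -0.13 for muscle (adjusted p = 0.374) and 0.17 for neural (adjusted p = 0.577; its mean of -0.010 and the direction of its test have the opposite sign). The medians of these lists depended on the scaling. With DESeq2 size factors and upper-quartile factors they were 0.12 and 0.11 for let-7, 0.089 and 0.075 for the miR-17 clusters, 0.34 and 0.35 for DLK1-DIO3 (21 of 28 above 0 with each), -0.27 and -0.31 for the erythrocyte list, -0.29 and -0.31 for liver, -0.24 and -0.25 for muscle and 0.050 and 0.028 for neural. In the lists given before they were 0.29 and 0.27 for platelet, 0.14 and 0.13 for myeloid, -0.39 and -0.42 for lymphocyte, -0.26 and -0.29 for fibrosis and hypoxia, 0.077 and 0.075 for inflammation, -0.42 and -0.42 for endothelial and stromal, and -0.75 and -0.73 for epithelial (0 of 9 above 0 with each). With library totals alone let-7 had 0.15, the miR-17 clusters 0.14, neural 0.096 and liver -0.33. With the haemolysis index as a covariate 2 medians changed sign, to 0.11 for the erythrocyte list (8 of 11 above 0) and 0.04 for muscle (4 of 6), and others moved to 0.27 for DLK1-DIO3 (21 of 28), 0.40 for the miR-17 clusters (11 of 11), 0.25 for platelet (9 of 12), -0.16 for lymphocyte, 0.050 for neural, 0.11 for endometriosis and 0.12 for inflammation. With no replicate block the median was -0.75 for liver, -0.21 for muscle and -0.06 for endometriosis. Examples by the naming rule that have not been given did not pass at month 15. Their log2 changes in the blood cell lists were 0.32 for miR-103a-3p/107, 0.31 for miR-25-3p, 0.21 for miR-15b-5p and -0.50 for miR-144-3p (erythrocyte), 0.49 for miR-191-5p, 0.44 for miR-197-3p and 0.38 for miR-28-5p (platelet), 0.74 for miR-223-3p, 0.52 for miR-142-3p and 0.37 for miR-155-5p (myeloid), and -0.49 for miR-181b-5p (lymphocyte). In the tissue lists they were 0.13 for miR-122-5p (higher in 4 of 8 baboons, while the mean of its paired differences in log2 CPM was -0.31, of the opposite sign), -0.45 for miR-192-5p/215-5p, -0.31 for miR-194-5p and -0.22 for miR-483-5p (liver), -0.50 for miR-378a-3p/378c/378d/378e, 0.95 for miR-133a-3p/133b, -0.094 for miR-1-3p and -0.16 for miR-499a-5p (muscle), 0.90 for miR-9-5p, 0.17 for miR-128-3p, -1.16 for miR-132-3p and 0.47 for miR-9-3p (neural), -1.72 for miR-203a-3p, -1.04 for miR-429 and -0.66 for miR-205-5p (epithelial), and -0.33 for miR-125b-5p (endothelial and stromal). In the families and clusters they were 0.35 for let-7d-5p, 0.34 for let-7f-5p, 0.32 for let-7i-5p and 0.18 for let-7g-5p (let-7), 0.41 for miR-20b-5p, 0.48 for miR-106a-5p/17-5p and 1.25 for miR-19b-3p (miR-17 clusters), and 2.17 for miR-1185-1-3p/1185-2-3p, 0.94 for miR-127-3p, 0.54 for miR-409-3p and 0.56 for miR-431-5p (DLK1-DIO3). In the fibrosis and hypoxia list miR-503-5p had 0.37 and miR-214-3p -1.44. None of the 29 members of C19MC, the placental cluster of primates, was counted often enough to be tested.

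Month 3 against month 0 asks whether plasma microRNAs differ early after inoculation. No microRNA passed the threshold by edgeR, and 5 had an unadjusted p under 0.05. The smallest p-values belonged to miR-127-5p (log2 -3.21, SE 1.08), miR-4676-5p (log2 0.84, SE 0.339, higher in 7 of 8 baboons) and miR-210-3p (log2 0.57, SE 0.236, higher in 7 of 8). The next 7 by p had log2 changes of 3.44 (miR-877-3p), -6.56 (miR-326-3p), 0.39 (let-7d-3p), -1.63 (miR-203a-3p), 0.35 (miR-20b-5p), 1.43 (miR-374a-3p) and -0.62 (miR-374a-5p); the fitted value of miR-326-3p is no measure of size, as most libraries held none of it. DESeq2 called 1, miR-326-3p, and limma-voom 0; with no low-count filter edgeR called 2, miR-24-3p and miR-326-3p. Both were all or none between libraries: miR-24-3p was at 0 in 27 libraries and at 1597 counts or more in the other 13, and miR-326-3p was at 0 in 30 and at 36 counts or more in the rest. No list passed.

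At month 6 no microRNA passed by edgeR, with 11 under an unadjusted p of 0.05. miR-1301-3p had the smallest p and was lower in 7 of 8 baboons, at 24.2 ± 7.36 against 44.3 ± 22.9 CPM (log2 -0.80, SE 0.233, adjusted p = 0.528). miR-210-3p was higher in 8 of 8 baboons (log2 0.74, SE 0.236, adjusted p = 0.568), and in the fibrosis and hypoxia list it passed when adjusted over the list alone (adjusted p = 0.0464). The next 8 by p had log2 changes of 0.89 (miR-4676-5p, higher in 8 of 8 baboons), -2.34 (miR-132-3p), 0.55 (miR-106a-5p/17-5p), 2.19 (miR-4286), 0.34 (miR-425-3p), -1.82 (miR-203a-3p), 0.35 (miR-503-5p) and 2.57 (miR-1249-3p). DESeq2 called 1, miR-24-3p, limma-voom 0, and edgeR without a low-count filter 1, also miR-24-3p. The endothelial and stromal list was lower, with 11 of 12 members below 0 and a median of -0.36 (camera adjusted p = 0.00978), a call that was lost with an estimated correlation (adjusted p = 0.391) and with fry (adjusted p = 0.651). miR-125b-5p (log2 -0.36, SE 0.308) and miR-99a-5p (log2 -0.35, SE 0.266) were among its members and did not pass singly.

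At month 9 no microRNA passed by edgeR, with 11 under an unadjusted p of 0.05. The smallest p-values were those of miR-210-3p (log2 0.78, SE 0.237, higher in 7 of 8 baboons, adjusted p = 0.762), miR-181a-5p (log2 -0.51, SE 0.175), miR-30e-5p (log2 0.58, SE 0.209) and miR-122-5p (log2 1.58, SE 0.589, higher in 5 of 8). The next 6 by p had log2 changes of -0.57 (miR-181a-2-3p), 1.17 (miR-365a-3p/365b-3p), 0.45 (miR-22-3p), -1.02 (miR-92a-1-5p), 0.71 (miR-574-3p) and -0.76 (miR-331-5p). Adjusted over the list alone, miR-210-3p passed in the fibrosis and hypoxia list (adjusted p = 0.0311), and miR-181a-5p and miR-30e-5p in the lymphocyte list (adjusted p = 0.0498 each). DESeq2 called 1, miR-24-3p, limma-voom 0, and edgeR without a low-count filter 2, miR-24-3p and miR-122-5p.

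The liver list was higher at month 9, with 8 of 8 members above 0 and a median of 0.72 (camera adjusted p = 0.00431). The median was 0.70 with DESeq2 size factors, 0.56 with upper-quartile factors and 0.33 with library totals alone, with 8 of 8 above 0 in each. The call was lost with an estimated correlation (adjusted p = 0.557), with fry (adjusted p = 0.343) and without the month 9 library of PA8001 (adjusted p = 0.0570). Its members included miR-122-5p, miR-192-5p/215-5p (log2 0.74, SE 0.453, higher in 5 of 8 baboons) and miR-194-5p (log2 0.62, SE 0.423, higher in 6 of 8). The neural list was lower, with 6 of 7 members below 0 and a median of -0.39 (camera adjusted p = 0.00431). Its call held with an estimated correlation (adjusted p = 0.0494) and was lost with fry (adjusted p = 0.310). Among its members were miR-9-5p (log2 -0.39, SE 0.398) and miR-132-3p (log2 -1.21, SE 0.975), microRNAs of neurons that other cells also make. The median of the neural list was -0.42, -0.54 and -0.73 under those 3 scalings. The endothelial and stromal list lay above 0 in 11 of 12 members with a median of 0.33 and did not pass (adjusted p = 0.166); with library totals alone its median was -0.04, with 4 of 12 above 0.

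Taking the 4 months after inoculation together, 3 microRNAs differed at any month: miR-210-3p, miR-30e-5p and miR-100-5p (each adjusted p = 0.0252; 29 of 318 had an unadjusted p under 0.05). The next 7 by p did not pass: miR-34c-5p and miR-99a-5p (adjusted p = 0.149 each), and miR-365a-3p/365b-3p, miR-223-5p, miR-1307-3p, miR-181a-5p and miR-187-3p (adjusted p = 0.157 each). This count was 0 without PA8001, 0 without PA8872, 0 without PA8873, 1 without PA8912, 0 with upper-quartile factors, library totals alone or the haemolysis index as a covariate, 1 with log2 total count as a covariate or with the baboon as a random effect, 7 with DESeq2 and 15 with no low-count filter. On the mean of the months after inoculation 1 microRNA, miR-210-3p, was higher, in 8 of 8 baboons (log2 0.86, SE 0.197, adjusted p = 0.0383; 17 unadjusted). It no longer passed without PA8001, PA8835, PA8872 or PA8914, each of which gave 0 calls, nor with upper-quartile factors, library totals alone, either of the planned covariates or miR-122-5p taken out, each 0. With no replicate block for the baboon 2 passed, with DESeq2 2 (miR-24-3p added), and with no low-count filter 2 others (miR-24-3p and miR-1260a/1260b). No list passed on the mean.

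Late months were set against early ones to ask directly whether the profile moved as time after inoculation went on. No microRNA passed by edgeR, with 16 under an unadjusted p of 0.05; DESeq2 called 2 (miR-30e-5p and miR-326-3p) and limma-voom 0. miR-30e-5p had the smallest p and was higher late in 8 of 8 baboons (log2 0.61, SE 0.146, adjusted p = 0.0669). It passed, and the count was 1, without PA8003, without PA8835 and without the month 15 library of PA8872, and also with DESeq2 size factors, with a mean count of 50 or more and in a fit of months 3, 6, 9 and 15 alone; with no low-count filter 3 others passed. The next by p, none of which passed, had log2 differences of -0.46 (miR-181a-2-3p), 2.05 (miR-127-5p), 0.36 (miR-22-3p), 1.05 (miR-3614-5p), -1.53 (miR-34c-5p), 0.40 (miR-210-3p), -0.24 (miR-628-3p) and -0.48 (miR-146a-5p). miR-181a-5p was lower late (log2 -0.37, SE 0.123, adjusted p = 0.466), and in the lymphocyte list both passed when adjusted over the list alone (adjusted p = 0.00231 for miR-30e-5p, adjusted p = 0.0259 for miR-181a-5p). No list passed. A comparison of month 15 with the mean of months 3, 6 and 9, chosen after the month 15 result was seen, called 2 over all microRNAs: miR-34c-5p (log2 -3.50, SE 0.807) and miR-30e-5p (log2 0.67, SE 0.164), each with adjusted p = 0.0387.

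The 4 comparisons share the month 0 libraries, which alone makes their changes alike. Across microRNAs, changes at months 6 and 15 had a covariance of 0.168, against a mean of 0.120 in simulations in which no month differed. Of 100 simulations 0 were as large. The simulations drew each microRNA on its own, without shifts shared between microRNAs, so their spread may be too narrow. They therefore cannot tell whether months 6 and 15 resembled each other beyond the shared month 0. For months 3 and 6 the covariance was 0.117 (55 of 100 as large), for months 3 and 9 0.0793 (99 of 100), for months 3 and 15 0.120 (57 of 100), for months 6 and 9 0.124 (53 of 100) and for months 9 and 15 0.101 (87 of 100). When changes of 4 baboons at a month were set against those of the other 4 at another month, over 70 divisions, the mean correlation across microRNAs lay between -0.158 and 0.018 for the 6 pairs of months.

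Red cell lysis at bleeding was followed by miR-451a, a red cell microRNA, against miR-23a-3p/23b-3p. Mean miR-451a was 1786, 1477, 1806, 1443 and 1215 CPM at months 0, 3, 6, 9 and 15, with SDs of 1869, 769, 1606, 785 and 883 (n = 8). These means lie far below those of the red cell microRNAs miR-16-5p and miR-486-5p given above. How well the index follows red cell lysis in these libraries was not tested. miR-23a-3p/23b-3p had means of 1497, 1981, 2108, 1459 and 2153 CPM with SDs of 955, 1557, 2106, 1278 and 1482. The haemolysis index was 0.83 lower at month 15 than at month 0 (SD 1.67, n = 8; lower in 5 of 8 baboons; exact p = 0.0938, adjusted p = 0.375), with the lowest library, the month 15 library of PA8872, at -3.43; without PA8872 the index was 0.26 lower (a change of -0.263). Changes were -0.17 at month 3, -0.16 at month 6 and 0.05 at month 9, with adjusted p of 0.896, 0.896 and 0.898. Log2 total count was 0.69 higher at month 15 (SD 0.907, higher in 7 of 8 baboons, 1.61-fold; exact p = 0.0625, adjusted p = 0.229), and 39.0 more rows had a count (SD 46.4, higher in 7 of 8; exact p = 0.0547, adjusted p = 0.219). Neither measure passed at the other months.

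For the median microRNA, the baboon accounted for 31.7% of the variance of log2 CPM, against 17.2% with permuted labels (permutation p = 0.0099, the smallest that 100 permutations can give). Month accounted for 7.38%, against 7.00% with permuted labels (permutation p = 0.356), and 58.6% was left over. With a mean count of 50 or more, the shares were 37.8% for baboon and 7.19% for month.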

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

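Chosen after the results were seen were the test of elapsed time, the tests of miR-24-3p on low counts and on its cluster, the reading of how much of each fold change was kept, and the alternatives with miR-122-5p taken out of the table; the month 9 result of the liver list was already known when the tests of miR-122-5p were written.

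At month 15, 13 microRNAs passed the threshold. Of 100 relabellings of months 0 and 15 within baboons, the real one included, 2 gave as many. This makes chance less likely for this count but does not exclude it. The highest other, 21, came from relabelling PA8915 alone, and leaving PA8915 out gave 20. PA8915 was also the only baboon with fewer counts at month 15 (885587) than at month 0 (1614219), so it runs against the depth difference as well. Against miR-122-5p taking most of the counts, 7 of the 13 stayed past the threshold with it taken out before scaling. This was exactly the bound set beforehand, with 92.0% of the log2 change kept at the median. Those that stayed were the 5 falls and, of the 8 rises, only miR-210-3p and miR-30e-5p, so the bound was met mostly by falls. The 6 that ended were all rises and kept an unadjusted p under 0.05. With log2 total count as a covariate 2 of the 13 stayed, few enough to meet what had been written beforehand for deeper libraries as the cause, but 86.9% of the log2 change was kept (median size 0.83 before and 0.81 after, SE 0.235 and 0.242); with the haemolysis index 3 stayed, again few enough, and 83.3% was kept (0.83 before and 0.68 after, SE 0.235 and 0.218). miR-210-3p and miR-30e-5p stayed with both covariates, and miR-34c-5p with the haemolysis index. Of the 11 calls that ended with the depth covariate 11 kept an unadjusted p under 0.05 (median log2 change over SE 3.66 before, 3.03 after). Of the 10 that ended with the haemolysis index 10 did (3.6 and 2.91). With the changes mostly kept and most calls ended, depth and red cell lysis cannot be told apart from a change with disease. Elapsed time, age and storage cannot be told apart from lesions either, with 0 baboons without inoculation among the samples, and the growth of lesions stays open, untested.

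miR-122-5p took between 0.307% and 78.6% of the counts, with PA8001 standing apart from the other baboons at month 0 (52.87%; others 0.969 to 20.7%), month 6 (51.04%; others 0.307 to 16.7%) and month 9 (78.64%; others 1.14 to 34.2%). Against amplification of 1 product, 5 of the 7 other liver-list microRNAs followed it within baboons, with it left out of the scaling, with a correlation over 0.5 and an adjusted permutation p under the threshold: miR-483-5p (r = 0.795, rho = 0.706), miR-885-3p (0.776, 0.811), miR-192-5p/215-5p (0.690, 0.708), miR-194-5p (0.674, 0.762) and miR-885-5p (0.565, 0.502), with adjusted p of r from 2.33e-05, set by the smallest p that the permutations can give (1e-05), to 0.00118. The median correlation of the 7 was 0.674, above that of all 10000 random lists (median -0.0601), 0.658 without the 2 libraries farthest from the median and 0.579 without PA8001, which is consistent with release from liver in some animals. The other 2, miR-483-3p (r = 0.284, adjusted p = 0.0596) and miR-148a-3p (r = 0.162, adjusted p = 0.362), did not pass. What moved with miR-122-5p was not confined to the list: miR-193b-5p (r = 0.739), miR-193a-5p (0.723) and miR-100-5p (0.71) followed it too, the last an endothelial and stromal microRNA that fell at month 15 (log2 -1.16, and -1.17 with the level of miR-122-5p as a covariate). Of the liver list, 2 of the 8 tested microRNAs are in another list too. PA8001 was high before inoculation, and no measure of liver injury is in the labels, so whether its liver differed stays untested.

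miR-24-3p, a member of the platelet list, had no count in 27 libraries and 1597 to 43201 counts in the other 13, which came from 6 baboons (4 from PA8003, 3 from PA8912, 2 from PA8001, 2 from PA8873, 1 from PA8835 and 1 from PA8915) and none from PA8872 or PA8914. Low depth is argued against, since the lowest level among libraries with counts would give at least 834 counts in each library at 0. Loss of the whole clusters from plasma is argued against as well, since miR-23a-3p/23b-3p never had under 545 counts. That its reads were placed in another row cannot be told: the row with the most opposite on and off pattern matched in 28 of 40 libraries, under the bound of 30 set beforehand, but that bound was wrong in design, as a row with counts of its own in every library cannot show such a pattern. How the rows were counted by the authors is not stated, so a biological explanation was not tested.

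The other relabellings gave these results. At months 3, 6 and 9 and for late against early the real count is 0, so 100 of 100 give as many by construction and say nothing of chance (highest other 0, 1, 2 and 25). For any month 1 of 100, the real one, gave as many as 3 (highest other 0). The real one is always counted, so 1 of 100 is the smallest result this test can give. It speaks against chance for this count but does not exclude it. The count was 0 without PA8001, PA8872 or PA8873. On the mean after inoculation 5 of 100 gave as many as the 1 real call (highest other 32), so chance cannot be excluded. A call was made in 4 of the other relabellings for the mean and in 9 for late against early; single ones gave 32 and 25 calls, several times the real counts, and whether a structure of the samples lies behind these was not tested.

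Of 100 groups of 8 libraries, 13 held a library far from the other 7. Its gap to the nearest, over the range of the group, lay above the 95% critical value of Dixon's test. In independent, normally distributed groups chance gives about 1 in 20. These groups reuse the same 40 libraries, and total counts and shares were taken without logs, so the 13 cannot be set against that rate. Besides the 3 shares of miR-122-5p in PA8001, total counts stood apart in PA8914 at month 3 (5243779 counts; others 816489 to 2510545) and in PA8912 at month 6 (5824111 counts; others 710943 to 2423703). In PA8835 low log2 CPM was seen for miR-191-3p at month 15 (5.318), miR-30e-5p at month 0 (11.44) and miR-342-3p at month 3 (8.325). High log2 CPM was seen for miR-126-3p in PA8873 at month 0 (16.50), miR-1307-3p in PA8914 at month 3 (8.479) and miR-23a-3p/23b-3p in PA8912 at month 9 (12.14). Low log2 CPM was seen for miR-23a-3p/23b-3p in PA8914 at month 15 (8.232) and miR-34c-5p in PA8001 at month 3 (0.08076).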

How the results depend on the processing

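Chosen after seeing the data were the alternatives with miR-122-5p taken out, with its level as a covariate, and without the PA8001 month 9 or the PA8872 month 15 library. Of 1547 values of the 64 named results under the alternatives, 203 lost their call and 22 gained one. Only the 13 results at month 15, the 3 for any month and the 1 for the mean had a call to lose. The 203 are therefore not to be read as a share of 1547. Of the 1308 values that have a sign (any-month values do not), 0 changed it. This says little of stability: the results were named for a small p or a large change in these same data. The alternatives also reuse most of the data, and the examples named from the lists are not in the tally. At month 15 log2 changes of miR-210-3p lay between 1.12 and 1.46 (highest adjusted p 0.0571), of miR-30e-5p between 0.81 and 1.08 and of miR-34c-5p between -4.24 and -3.08. Counts below are calls at month 15 (13 in the reported fit), any month (3), mean after inoculation (1), late against early (0) and months 3, 6 and 9 (0 each); counts not named stayed within 1.5 times.

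With DESeq2 size factors late against early gave 1. Upper-quartile factors gave 0 for any month and 0 for the mean, and library totals alone 4 at month 15, 0 for any month and 0 for the mean; the median log2 change of all rows at month 9 moved from 0.05 to -0.12 and -0.28 under these. With no filter except 1 count there were 2, 1 and 2 calls at months 3, 6 and 9, 15 for any month, 2 for the mean and 3 late against early; a mean count of 50 or more gave 1 late against early. DESeq2 gave 1, 1 and 1 at months 3, 6 and 9, 7 for any month, 2 for the mean and 2 late against early. limma-voom with the baboon as a random effect gave 1 for any month. With no replicate block there were 2 calls at month 15 and 2 for the mean. Fitting only the samples of the months compared, with fewer samples and 265 rows tested at month 15, gave 0 at month 15 and 1 late against early. The haemolysis index as a covariate gave 3 at month 15, 0 for any month and 0 for the mean, and log2 total count 2, 1 and 0. With miR-122-5p taken out there were 8 at month 15 and 0 for the mean, and with its level as a covariate 8 at month 15. Without the PA8872 month 15 library there were 4 at month 15 and 1 late against early. Leaving out each baboon gave 2 to 20 at month 15, 0 to 4 for any month, 0 to 1 for the mean, 0 to 1 late against early and 0 at months 3, 6 and 9. What caused these differences was not tested.

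Lists past the threshold numbered 0, 1, 2 and 1 at months 3, 6, 9 and 15. With an estimated correlation they were 0 at month 6, 1 at month 9 and 0 at month 15, and with fry 0, 0 and 0. The haemolysis index as a covariate gave 1 at month 3, 2 at month 6, 3 at month 15 and 1 for the mean (0 in the reported fit); the miR-17 clusters were among them each time, but none of these lists passed with that covariate and an estimated correlation (for the miR-17 clusters adjusted p = 0.415, 0.339, 0.471 and 0.230). At month 15 the miR-17 clusters with that covariate passed with fry (adjusted p = 0.0154), with 11 of 11 members above 0 and 4 past the threshold over the list alone; at months 3 and 6 and for the mean fry did not pass (adjusted p = 0.430, 0.168 and 0.0543). miR-122-5p taken out gave 2 at month 15. Without the PA8001 month 9 library there was 1 at month 9 and 0 at month 15, and without the PA8872 month 15 library 0 at month 15. The cause was not tested.

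The haemolysis index at month 9 (0.05 above month 0) was -1.52 with the mean of 3 references, one of which, miR-24-3p, had no count in 27 libraries; the index with these was -0.597 at month 3, -1.54 at month 6 and -1.16 at month 15 (-0.174, -0.156 and -0.834 in the reported form). Leaving out each baboon gave -0.349 to 0.0465 at month 3, -0.366 to 0.041 at month 6 -0.236 to 0.292 at month 9 and -1.0 to -0.263 at month 15, the last without PA8872. Depth limits the scarce microRNAs: a 0 excludes only levels above 0.374 to 3.97 CPM.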

Other observations

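All that follows was chosen after the month 15 result was seen, except the fits under settings fixed beforehand. MicroRNAs of the families related to miR-34c-5p were looked at beside it. miR-34b-5p, made from the same transcript as miR-34c-5p, had too few counts for the reported fit: 87 counts over the 8 libraries of month 0 and none at month 15. Its pooled TMM-scaled level of 7.18 CPM at month 0 was 44-fold the level of the 3 counts that a 0 over the pooled month 15 libraries allows. It was at 0 in 4 of the 8 month 0 libraries, and PA8912 held 55 of the counts. With PA8912 left out of both months 32 counts and 3.18 CPM remained, 15.1-fold the level that a 0 then allows. Neither fold is a lower bound, as the error of the month 0 level and the spread between baboons are left out. With no low-count filter miR-34b-5p passed the threshold. The other arms held few counts at either time: miR-34c-3p had 10 at month 0 and 0 at month 15, and miR-34b-3p had 0 and 2. miR-34c-5p summed to 480 counts at month 0, 242 at month 3, 191 at month 6, 222 at month 9 and 28 at month 15; PA8912 held 298 of the month 0 counts, and without it the sums were 182, 190, 152, 174 and 23. miR-449a/449b-5p was lower at month 15 without passing in the reported fit (log2 -0.60, SE 0.194, adjusted p = 0.0792), though it passed in 7 of 25 alternatives, and miR-34a-5p, from another gene, had 688 CPM over the pooled libraries of month 0 and 721 CPM over those of month 15.

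Beside miR-24-3p, 5 tested rows were all or none, meaning at 0 in 4 or more libraries and otherwise at 20 counts or more: miR-652-3p (0 in 5 libraries, otherwise 361 counts or more), miR-760 (13, 31), miR-326-3p (30, 36), miR-6891-5p (17, 22) and miR-1294-5p (23, 23). None is among the microRNAs that passed at month 15.

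A candidate explanation for the platelet list lying above 0 at month 15 (median 0.41) is more platelets or platelet vesicles in that plasma. The list's median lay above that of the other tested microRNAs in 5 of 8 baboons (mean difference 0.24, SD 0.378; exact p = 0.133), too few to tell. Deeper libraries at month 15 stay open too: with log2 total count as a covariate the list's median was 0.2033 in place of 0.4085. Red cell lysis stays open as well: with the haemolysis index as a covariate it was 0.2544, with 9 of 12 members above 0. Its abundant members miR-126-3p (60525 CPM) and miR-126-5p (29495 CPM) are also made by endothelium, and 2 of its 12 tested members are in another list too.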
